A study of Mus musculus with 33 samples.

How the data were processed

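RNA was sequenced from mouse cardiomyocytes, the contractile cells of the heart, and the labels give the molecule as nuclear RNA. Libraries were made with a KAPA kit that removes ribosomal RNA, per the labels' protocols. The series holds 33 samples from 4 mouse lines. A cardiomyocyte-specific knockout of Ptpmt1, the phosphatase of the inner mitochondrial membrane that makes phosphatidylglycerol for cardiolipin synthesis, is part of every line. The FST line, named as in the sample titles, combines it with a mutation of Eif2a. The PHT line combines it with a knockout of Hri and the PTGC line with a knockout of Gcn2, and another line carries the Ptpmt1 knockout alone. Eif2a, as used in the labels, is the alpha subunit of translation initiation factor eIF2, whose phosphorylation by the kinases Gcn2, Hri and others starts the integrated stress response (ISR), a programme of genes driven by the transcription factor Atf4. The gene of that subunit has the symbol Eif2s1, those of Gcn2 and Hri are Eif2ak4 and Eif2ak1, and the symbol Eif2a belongs to another initiation factor. The 6 samples of the Ptpmt1-only line had no column in the tables at hand and are not analysed here, which left 27 libraries. What the line names stand for and the age of the animals are not given in the sources used here.

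The deposited values are a normalized signal, 1 value per gene and library, in 3 tables that hold the FST, PHT and PTGC lines. Reads were processed with STAR 2.5.3a and DESeq2 1.12.4 on mm10, per the submitters' processing notes, which give no roles. The read counter, the annotation and the strand setting are not given in the sources used here, so reads of genes that overlap, on either strand, cannot be assigned. Within a column of these deposited signal values all entries were whole multiples of 1 step, as counts divided by a size factor are. Dividing by the step gave whole reads within a tolerance of 0.1 for 100% of values, and these recovered reads give the depths below and feed the count tests. In one PHT column, Ptpmt1 knockout replicate 3, the step was 1.0004, so its values are nearly reads. Each table has 32245 genes, given by symbol only, and 26 of these symbols had been turned into dates by a spreadsheet. The tables were normalized separately, so every test stayed within 1 table, and levels are not compared between tables. Sample columns were matched to samples by title, and 0 columns of values were left without a sample.

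Genes were tested with limma 3.58.1 in R 4.3.3 (intensity trend in the prior variance, no robust prior) on log2(value + 1), in 1 fit per table with all groups, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. A gene was tested where its value reached 10 in at least as many libraries as the smallest group has, which left 13896 genes in FST, 14965 in PHT and 14128 in PTGC. Called means an adjusted p under that threshold. The interaction is the difference between the effect of the Ptpmt1 knockout on the second mutation and its effect without it. It was tested in FST and PHT, while the PTGC table holds neither single mutant, so that line has 1 comparison. This makes 13 comparisons. Values are group means ± SD of normalized counts, log2 fold changes are ± SE, and adjusted p without another name is limma's.

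Gene lists were compared with all other genes by camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 3 tested genes. The 37 lists covered ISR regulators, amino acid and one-carbon synthesis, amino acid transport, tRNA synthetases, mitochondrial proteostasis, the ER unfolded protein response, oxidative phosphorylation complex I and complexes II to V, mitochondrially encoded genes, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, the TCA cycle, fatty acid oxidation, glycolysis, cardiolipin synthesis, mitochondrial dynamics and mitophagy, fetal and stress genes of the heart, extracellular matrix remodelling, the cell cycle, p53 targets, Nrf2 targets, interferon response, immediate early genes, eIF2 kinases, sex-linked genes and nuclear-retained RNAs. Marker lists covered cardiomyocytes, atrial cardiomyocytes, fibroblasts, endothelial cells, mural cells, macrophages, lymphocytes, erythroid cells, epicardium, Schwann cells and adipocytes. The first 4 of these lists are called the ISR lists.

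The rule for named genes took the targeted genes, a panel of 14 ISR and cardiac stress genes, the largest rises and falls among called genes with a mean of at least 50 in the higher group (6 each way for the Ptpmt1 knockout against control, the double mutants against the Ptpmt1 knockout and the PTGC comparison, 3 elsewhere, 6 by p for interactions, without clone names), and up to 4 members of a list by p. A few genes outside the rule are named as such. Groups, lists, this rule, the tests and most alternatives were fixed before the data were examined. The design assumed normalized values, as found.

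Alternatives were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, pseudocounts of 0.5 and 8, no filter and a filter of 100, TMM scaling, a robust prior, a fit of only the groups compared, leaving out each library in turn, camera with an estimated correlation, and fry. A sex term, and leaving out both FST libraries that stand apart, were added after seeing the data. On simulated counts with 200 genes changed in 13896, limma recovered 52.2% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes for the FST Ptpmt1 knockout. The shares were 59.7%, 91.0% and 98.5% for the PHT one over 14965 genes and 41.8%, 94.0% and 100% for PTGC over 14128. False calls were 6 of 167, 8 of 174 and 3 of 160 for limma, and 24 of 195 for DESeq2 in FST. Camera called the 1 list simulated as rising and 0 of 30 unchanged lists in each table. Genes were drawn independently and the unchanged lists at random. False calls for lists whose genes vary together, or from sample structure, were not measured. No share is given for low genes.

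The depth was 1887978 to 12583868 reads in genes per FST library, 10739569 to 19405261 in PHT and 10795644 to 19326112 in PTGC. Ratios that rest on few reads are given with a 95% interval, which covers counting error only. Pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.22 to 42.2. Replicates are numbered in accession order, a name only. The titles give each library its own identifier but do not state that each is a separate animal, so p-values measure the spread between these samples, which may be technical. A male pattern means a Y-linked Ddx3y value above 100. Gene positions are those of GENCODE for GRCm38 (mm10), matched by symbol for 31347 of 32243 symbols. Figures were drawn with matplotlib 3.10.9.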

Results

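The expression of genes in cardiomyocytes was compared between mice without Ptpmt1 and controls, and between mice with and without a second mutation in the pathway that phosphorylates eIF2. The FST table held 12 libraries, with 3 each of control, Eif2a mutant, Ptpmt1 knockout and the double mutant of both. The PHT table held 9, with 2 controls, 2 labelled Hri knockout, 3 Ptpmt1 knockouts and 2 doubles labelled as both. The PTGC table held 6, with 3 controls and 3 doubles labelled Ptpmt1 and Gcn2 knockout. A pair of FST libraries stood apart in genes with reads and in correlation, and 1 of them in depth. Double replicate 2 had only 1887978 reads in genes, and 15336 genes with reads. Eif2a mutant replicate 1 had 6535417 reads and 15157 genes with reads, against 17567 or more in every other FST library. Their median correlations with the other FST libraries were 0.954 and 0.945, against 0.970 or more elsewhere. Control 3 and Ptpmt1 knockout 3 in FST differed from the other libraries of their groups, with a chi-square per degree of freedom of 14.8 and 17.0, and of 19.8 and 22.3, against 3.67 and 6.78 between the others. In PTGC control 3 did (28.1 and 42.2, against 9.80). A male expression pattern was seen in 1 of 3 controls, 3 of 3 Eif2a mutants, 3 of 3 Ptpmt1 knockouts and 2 of 3 doubles in FST. In PHT it was seen in 0 of 2 controls, 2 of 2 Hri knockouts, 1 of 3 Ptpmt1 knockouts and 2 of 2 doubles, and in PTGC in 2 of 3 libraries of each group. In PHT the single and double Hri groups therefore differed from control in sex in every library.

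Ptpmt1, at chromosome 2, 90908716 to 90918258 in GRCm38, fell wherever its knockout was labelled. In FST its normalized count was 163 ± 10.3 in control (n = 3), 157 ± 6.69 in the Eif2a mutant, 35.5 ± 4.71 in the Ptpmt1 knockout and 45.2 ± 4.87 in the double. The log2 fold change was -2.17 ± 0.17 in the knockout against control (adjusted p = 1.12e-05) and -1.78 ± 0.17 in the double against the Eif2a mutant (adjusted p = 0.000358). Against control the double was at -1.83 ± 0.17 (adjusted p = 0.00024), and against the Ptpmt1 knockout at 0.34 ± 0.17 (adjusted p = 0.396), which was not called. In PHT it was 265 ± 33.6 in control (n = 2), 264 ± 28.1 in the Hri knockout, 48.8 ± 13.8 in the Ptpmt1 knockout (n = 3; -2.44 ± 0.22, adjusted p = 6.17e-05) and 77.4 ± 0.957 in the double (n = 2; -1.76 ± 0.24, adjusted p = 0.0136). In PTGC it fell from 328 ± 35.4 to 71.2 ± 4.48 (-2.18 ± 0.14, adjusted p = 3.9e-06). No knockout or double library overlapped a control library in any table. Of the control level, 21.8%, 18.4% and 21.7% was left in the FST knockout, PHT knockout and PTGC double, a share that may include reads of Kbtbd4, whose exons overlap those of Ptpmt1. In PHT the call of the double against control was lost without double replicate 1 or 2 or control replicate 1 or 2 (adjusted p = 0.0525, 0.107, 0.147 and 0.327). Against the Hri knockout the call (-1.75 ± 0.24, adjusted p = 0.0231) was lost without Hri knockout replicate 1 or 2 or double replicate 2 (adjusted p = 0.058, 0.219 and 0.147).

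The targeted kinase genes were not called in any comparison. Eif2ak1, which encodes Hri, the kinase activated by haem shortage and mitochondrial stress, lies at chromosome 5, 143817788 to 143904251. It had a normalized count of 569 ± 29.8 in PHT controls, 403 ± 18.8 in the libraries labelled Hri knockout (-0.5 ± 0.12, adjusted p = 0.812, and 0.0119 adjusted over the list alone) and 510.1 ± 48.9 in the doubles (-0.16 ± 0.12, adjusted p = 0.825). That is 70.8% of control (95% interval 59.0 to 84.9) in the single and 89.5% (74.6 to 107) in the double. The double had 126% (105 to 152) of the level in the single, an unadjusted interval (adjusted p = 0.785). Eif2ak4, which encodes Gcn2, the kinase that senses uncharged tRNA, lies at chromosome 2, 118388618 to 118475234. It was 392 ± 125 in PTGC controls and 350.3 ± 36.8 in the doubles (-0.11 ± 0.21, adjusted p = 0.836), 92.8% (67.6 to 127) of control. A deletion of part of either transcript would not show in values per gene, so these labels could not be checked and the groups are named as labelled. Eif2s1, at chromosome 12, 78861819 to 78887010, was 701 ± 30.6 in FST control and 844 ± 210.4, 812 ± 136 and 849 ± 74.7 in the Eif2a mutant, Ptpmt1 knockout and double (adjusted p = 0.686, 0.613 and 0.561). A point mutation would not show there either. The gene with the symbol Eif2a, at chromosome 3, 58525821 to 58557501, was 563 ± 5.87 in FST control and 680.1 ± 93.0 in the Ptpmt1 knockout (adjusted p = 0.248).

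**Figure D1:**
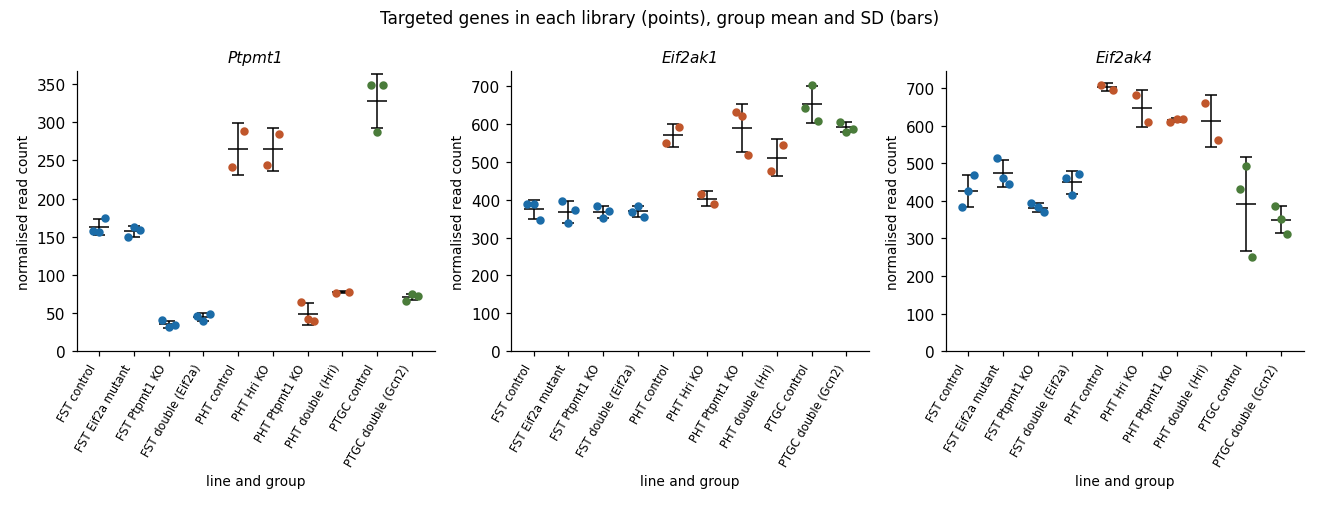
Normalized counts of the targeted genes in every library, by group, with points for libraries and bars for the group mean and SD. Ptpmt1 lies near 35.5 in the FST Ptpmt1 knockout and 163 in its control, while Eif2ak1 in the PHT doubles lies near 510.1 and in control near 569.

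Loss of Ptpmt1 alone was tested in FST first. Genes of the ISR made up most of the largest rises. Asns, which makes asparagine, rose from 232 ± 25.0 to 1205 ± 238 normalized counts (log2 fold change 2.36 ± 0.15, adjusted p = 1.56e-06, n = 3 and 3). Trib3, a pseudokinase induced by Atf4, rose from 14.3 ± 0.957 to 266 ± 166 (3.96 ± 0.34, adjusted p = 2.51e-05), and Mthfd2, a mitochondrial one-carbon enzyme, from 254 ± 30.3 to 957 ± 276 (1.88 ± 0.17, adjusted p = 5.35e-05). Atf4 itself, at chromosome 15, 80255184 to 80257541, rose by 0.97 ± 0.13 (adjusted p = 0.00285) and Atf5, a related factor of the mitochondrial stress response, by 1.79 ± 0.31 (adjusted p = 0.0157). The serine synthesis enzymes Phgdh (1.32 ± 0.21, adjusted p = 0.00688) and Psat1 (1.06 ± 0.15, adjusted p = 0.00308) rose too. The largest fold rises were in Trim66, a chromatin reader (6.16 ± 0.78, adjusted p = 0.00171, with 1 read in the controls and a ratio of 383, 95% interval 67.8 to 15049.6) and Slc7a3, a cationic amino acid transporter (4.78). The glutathione-degrading enzyme Chac1 (4.42), Trib3, the cystine transporter Slc7a11 (3.88) and the cytochrome b5 reductase Cyb5r2 (3.60) followed. The largest falls were in Ptpmt1 and the mitochondrial RNA-processing RNA Rmrp (-1.53 ± 0.30, adjusted p = 0.0341, 0.0589 with edgeR). They were followed by the actin-binding Tmsb10 (-0.86), Gja5, the atrial and conduction-system connexin (-0.78), Arhgef4 (-0.76) and Atp5k, a subunit of ATP synthase (-0.74). Of the cardiac stress genes, Nppa (0.07, adjusted p = 0.93), Nppb (0.15, 0.82), Myh7 (-0.47, 0.144) and Myh6 (-0.35, 0.463) were not called. The ISR factor Ddit3 (1.10, 0.243) was not either, and Gdf15 and Fgf21 were too low to be tested. In all, 70 genes were called, 45 higher and 25 lower, and 25 of the 45 belong to the ISR lists, of whose members 57 were tested. The count was 25, 21 and 34 without control replicate 1, 2 and 3, 44 and 36 without knockout replicate 1 and 2, and 857 without knockout replicate 3, 417 higher and 440 lower. With a sex term it was 21, with only these groups fitted 27, and with DESeq2 353, 154 higher and 199 lower.

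Groups of genes moved together. Among 14 genes of amino acid and one-carbon synthesis 8 rose (13 adjusted over the list alone), with a median log2 fold change of 1.01 (camera adjusted p = 2.88e-25, and adjusted p = 0.0535 with an estimated correlation). Gpt2, which makes alanine, was among them (1.53 ± 0.22). Among 14 ISR regulators 5 rose (9 adjusted over the list alone; median 0.83, adjusted p = 1.18e-13, and adjusted p = 0.0826 with an estimated correlation). Of 9 amino acid transporters 4 rose (8 adjusted over the list alone), such as Slc7a1 (0.62 ± 0.09) and Slc1a4 (1.43 ± 0.23). The median was 0.92 (adjusted p = 1.72e-13, and adjusted p = 0.0687 with an estimated correlation). Of 20 tRNA synthetases, the enzymes that charge tRNAs, 8 rose (11 adjusted over the list alone). Cars (1.0 ± 0.12), Lars (0.90 ± 0.13), Iars (0.70 ± 0.10) and Gars (0.67 ± 0.10) are examples, and the list had adjusted p = 2.38e-15, and adjusted p = 0.121 with an estimated correlation. These 4 lists stayed called whichever library was left out. Glycolysis was lower: of 20 genes 2 fell (8 adjusted over the list alone), Hk1 (-0.57 ± 0.11) and Pfkl (-0.59 ± 0.12). The median was -0.23 (adjusted p = 8.41e-09, and adjusted p = 0.132 with an estimated correlation). Complexes II to V of oxidative phosphorylation were lower, with 1 of 33 genes falling and 2 adjusted over the list alone (median -0.19, adjusted p = 1.78e-08, and adjusted p = 0.27 with an estimated correlation). The TCA cycle was lower too (0 of 18 fell, median -0.12, adjusted p = 0.00418, and adjusted p = 0.452 with an estimated correlation). Cardiomyocyte markers were lower as a list, while 0 of 17 fell one by one and 6 did adjusted over the list alone (median -0.25, adjusted p = 4.49e-06, and adjusted p = 0.0826 with an estimated correlation). Mybpc3, a thick filament protein, was at -0.46 ± 0.10 (adjusted p = 0.0567). The pericyte gene Cspg4 fell (-0.53 ± 0.09, adjusted p = 0.0153). Erythroid markers moved with these: they were lower as a list (0 of 10 fell, median -0.63, adjusted p = 0.00359, and adjusted p = 0.521 with an estimated correlation). Erythroid genes held 0.134% ± 0.0861 of the signal in the knockout and 0.208% ± 0.112 in control (n = 3 and 3, exact permutation p = 0.5, where 0.1 is the smallest possible). That list was not called without knockout replicate 1 (adjusted p = 0.0698) or control replicate 2 (0.171). Mitochondrially encoded genes were higher with no member called (median 0.54, adjusted p = 0.0256, and adjusted p = 0.544 with an estimated correlation), a call lost without knockout 3 or control 3 (0.199 and 0.968). All 28 named genes called here had groups that did not overlap, which chance gives for 10% of genes picked without regard to their values, while these were picked for their difference. Calls were lost for Atf5 without control replicate 1, 2 or 3 (adjusted p = 0.0678, 0.075 and 0.0637). The same held for Chac1 (0.056, 0.0558 and 0.0529). Calls were lost without control 1 or 2 for Phgdh (0.0514 and 0.0558) and Gja5 (0.0656 and 0.077), without control 1 or 3 for Slc1a4 (0.0514 and 0.0526) and without control 2 or 3 for Slc7a3 (0.0717 and 0.0529). Those of Slc7a11, Cyb5r2, Rmrp, Tmsb10, Cspg4 and Pfkl were lost when any library other than knockout replicate 3 was left out (adjusted p = 0.0534 to 0.194). Those of Atp5k and Hk1 were lost without each control and 1 knockout, replicate 1 and 2 in turn (0.0666 to 0.158), and that of Arhgef4 without control 1 or 2 or knockout 2 (0.153 to 0.219).

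The same question was asked in PHT, with 3 knockouts and 2 controls. Asns rose from 306 ± 19.5 to 1366 ± 259 (2.14 ± 0.17, adjusted p = 3.1e-05), Atf5 from 170.1 ± 17.9 to 789 ± 168 (2.19 ± 0.17, adjusted p = 3.1e-05) and Mthfd2 from 385 ± 69.9 to 1247 ± 250.1 (1.69 ± 0.16, adjusted p = 6.17e-05). Atf4 (0.87 ± 0.12, adjusted p = 0.00191), Ddit3, a factor induced late in the ISR (1.34 ± 0.22, 0.00907), Phgdh (1.26 ± 0.12, 6.97e-05) and Psat1 (0.64 ± 0.11, 0.0135) also rose. The largest rises were in Chac1 (6.0 ± 0.55, adjusted p = 6.17e-05, 3 reads in the controls and a ratio of 102, interval 37.5 to 536) and Trim66 (5.81, 2 reads in the controls, ratio 85.9, interval 27.0 to 815). Slc7a11 (4.29), Slc7a3 (4.23), Trib3 (3.57) and Cyb5r2 (3.19) followed. Among falls with a mean of at least 50 there were Ptpmt1 and Zfp979, a zinc finger gene at chromosome 4, 147611937 to 147642513 (-1.78 ± 0.34, adjusted p = 0.0349). Nppa (0.03, adjusted p = 0.999), Nppb (0.08) and Gdf15 (2.91, adjusted p = 0.252) were not called. By group, 9 of 14 amino acid and one-carbon genes rose (12 adjusted over the list alone), such as Aldh1l2 (1.48 ± 0.14). The list had adjusted p = 2.18e-47, and adjusted p = 0.0396 with an estimated correlation. Of 9 transporters 6 rose (7 adjusted over the list alone), such as Slc7a5 (1.10 ± 0.11), with adjusted p = 2.09e-24, and adjusted p = 0.0396 with an estimated correlation. Of 16 ISR regulators 7 rose (12 adjusted over the list alone; adjusted p = 7.61e-36, and adjusted p = 0.053 with an estimated correlation). Of 20 tRNA synthetases 7 did (11 adjusted over the list alone; adjusted p = 1.25e-20, and adjusted p = 0.0727 with an estimated correlation), such as Sars (0.71 ± 0.08). Cox6a2, the heart form of a cytochrome oxidase subunit, rose by 1.25 ± 0.14 (adjusted p = 0.000488), and Herpud1, of ER-associated degradation, by 0.80 ± 0.10 (0.00144). Erythroid markers were lower as a list in the same libraries (0 fell, 8 adjusted over the list alone, median -1.11, adjusted p = 1.09e-10, and adjusted p = 0.348 with an estimated correlation). They held 0.347%, 0.321% and 0.0727% of the signal in the knockouts against 0.479% and 0.403% in the controls. Mitochondrially encoded genes were higher (0 rose, 3 adjusted over the list alone, median 0.17, adjusted p = 0.000808, and adjusted p = 0.472 with an estimated correlation), a call lost without control 1 (0.5). They held 1.82%, 1.76% and 1.87% of the signal in the knockouts, 1.25% and 1.58% in the controls and 1.56% and 1.61% in the doubles. Atrial markers were higher (0 rose, 3 adjusted over the list alone, adjusted p = 0.00335, and adjusted p = 0.348 with an estimated correlation), a call lost without control 2 (0.0938). Extracellular matrix genes were lower (median -0.25, adjusted p = 0.022, and adjusted p = 0.436 with an estimated correlation) and epicardial markers higher (median 0.20, adjusted p = 0.0459, and adjusted p = 0.423 with an estimated correlation) with no member called. The first was lost without knockout 1 or 2 or control 1 (0.27, 0.0921 and 0.327), the second in 4 of the 5 fits that left out a library (0.0594 to 0.188).

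In all, 45 genes were called in the PHT knockout, 42 higher and 3 lower, and 29 of the 42 were among 59 tested members of the ISR lists. The count was 27 without control 1, 21 without control 2 and 24 without knockout 2, and 69 with DESeq2. All 26 named genes called had groups that did not overlap (20% by chance). Atf4, Lars, Slc3a2, Slc7a11, Aars, Psat1 and Zfp979 lost the call without control 1 or 2. Cyb5r2 lost it without control 1, and Trib3, Ddit3, Cars, Slc6a9 and Stc2 without control 2. Ddit3, Cyb5r2, Slc7a11, Aars, Psat1 and Zfp979 lost it without knockout 2 (adjusted p = 0.0517 to 0.11). Psat1 and Zfp979 lost it without knockout 3 (0.0577 and 0.0537), and Zfp979 without knockout 1 (0.135). The other named calls stayed whichever library was left out. Both lines shared calls: 28 genes were higher in both knockouts, where independent lists of these sizes would share 0.136, and Ptpmt1 was the 1 gene lower in both. Of the 45 genes that rose in FST, 43 had a positive log2 fold change in PHT, with medians of 0.92 and 0.68. Over 13873 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.308 (jackknife SE 0.118) and Spearman's rho 0.251, and r was 0.554 for genes with a mean of at least 100. Zfp979 was called in opposite directions, at 2.15 ± 0.41 in the FST knockout (adjusted p = 0.0336) and as above in PHT. No test compared the tables directly.

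**Figure D2:**
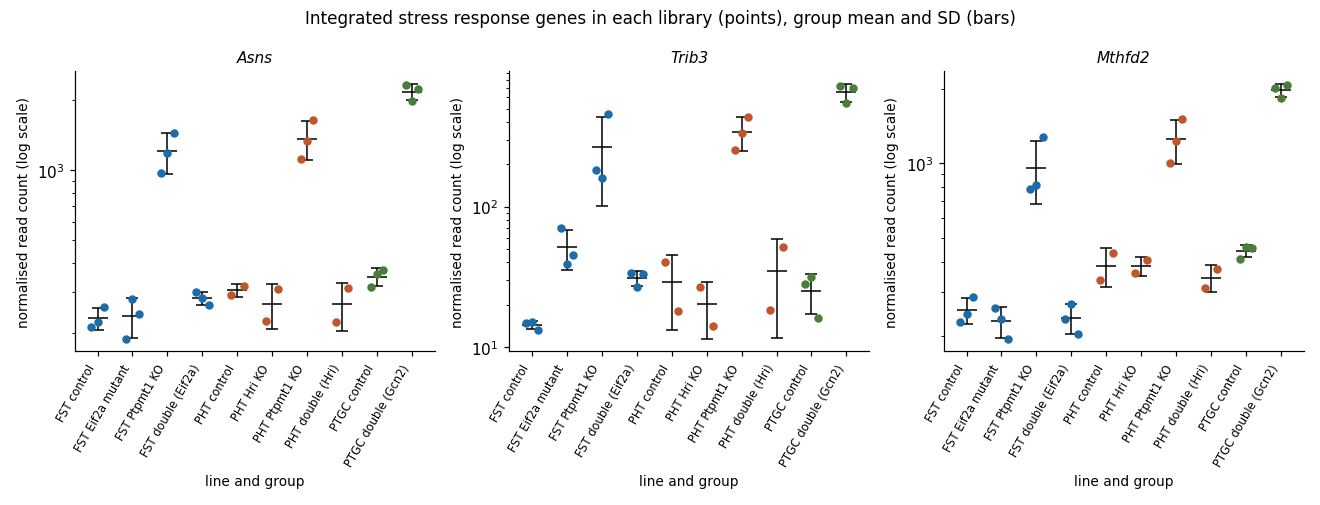
Normalized counts of ISR genes in every library, by group, on a log axis, with points for libraries and bars for the group mean and SD. Asns lies near 1205 in the FST Ptpmt1 knockout and near 282 in the FST double, and near 1366 and 267 in PHT.

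The Eif2a mutation alone changed few genes. Slc2a3, a glucose transporter, rose from 342 ± 33.5 to 804 ± 112 (1.23 ± 0.12, adjusted p = 0.000344, n = 3 and 3), Hjv, the co-receptor haemojuvelin of iron homeostasis, from 98.6 ± 14.7 to 227 ± 22.2 (1.20 ± 0.14, 0.00329), and Tppp3, a tubulin-binding protein, from 29.0 ± 2.51 to 90.1 ± 10.6 (1.6 ± 0.26, 0.0456). R3hcc1 fell from 222 ± 20.8 to 105 ± 12.3 (-1.07 ± 0.14, 0.00813). The fifth call was Bmp10, an atrial growth factor (0.55 ± 0.08, 0.0236). The atrial marker list was higher (1 of 6 rose, 2 adjusted over the list alone, median 0.27, adjusted p = 0.00422, and adjusted p = 0.248 with an estimated correlation). Glycolysis was higher too (0 rose, 6 adjusted over the list alone, median 0.18, adjusted p = 5.83e-05, and adjusted p = 0.588 with an estimated correlation), with Hk2 at 0.48 (adjusted p = 0.196). The p53 targets were higher as well (0 rose, 4 adjusted over the list alone, median 0.18, adjusted p = 0.00415, and adjusted p = 0.486 with an estimated correlation). The ISR regulators were higher as a list (0 rose, 1 adjusted over the list alone, median 0.33, adjusted p = 0.0366, and adjusted p = 0.817 with an estimated correlation). That call was lost without mutant 2 or 3 or control 3 (0.134, 0.0846 and 0.152). Signs of RNA quality moved with these lists: mitochondrially encoded genes (median 0.34, adjusted p = 0.0296, and adjusted p = 0.817 with an estimated correlation) and nuclear-retained RNAs (median 0.22, adjusted p = 0.0447, and adjusted p = 0.762 with an estimated correlation) were higher with no member called. The first was lost without mutant 1 or 2 or control 3 (0.195, 0.0688 and 0.207, the last with its direction turned), the second without mutant 2 or 3 or control 3 (0.127, 0.105 and 0.305). Of single ISR genes none was called by limma: Asns was at 0.02 (adjusted p = 0.982), Atf4 at 0.05 (0.931), Mthfd2 at -0.15 (0.843) and Trib3 at 1.73 ± 0.34 (0.155, and 0.0018 adjusted over the list alone). Genes of amino acid and one-carbon synthesis had a median of -0.01 and a mean of 0.03 (adjusted p = 0.359). Limma called 5 genes, with 1108 at an unadjusted p under 0.05, edgeR 6 and DESeq2 47. The groups of all 5 did not overlap (10% by chance). Slc2a3 and Hjv stayed called whichever library was left out, R3hcc1 was not called without control 1 or 2 (adjusted p = 0.113 and 0.0965), Bmp10 was called only without control 2 (otherwise 0.063 to 0.252) and Tppp3 in no such fit (0.0644 to 0.373). The count was 2 without control 1 and 3 without control 2, mutant 2 or mutant 3.

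When both mutations were present in FST, ISR genes were lower than in the Ptpmt1 knockout. Asns was at 282 ± 18.5 in the double against 1205 ± 238 in the Ptpmt1 knockout (-2.07 ± 0.15, adjusted p = 9.99e-06, n = 3 and 3), Mthfd2 at 236 ± 32.9 against 957 ± 276 (-1.99 ± 0.17, 5.03e-05) and Trib3 at 30.9 ± 3.83 against 266 ± 166 (-2.91 ± 0.34, 0.000775). Atf4 (-0.74 ± 0.13, 0.0125), Atf5 (-1.58 ± 0.31, 0.026), Phgdh (-1.39 ± 0.21, 0.00549) and Psat1 (-0.89 ± 0.15, 0.00887) were lower too. The largest falls were in Zfp990, a zinc finger gene at chromosome 4, 145510759 to 145539188 (no read in the doubles and at least 59.3-fold lower against a floor of 3 reads over the group, adjusted p = 0.0335) and Slc7a3 (-5.42). Trim66 (-5.03), Cyb5r2 (-4.27), Chac1 (-3.76) and Slc7a11 (-3.60) followed. The largest rises were in Rnf17, a Tudor-domain gene of the germline (2.55 ± 0.36, adjusted p = 0.00379), the aldo-keto reductase Akr1e1 (2.54), Tnfrsf1b, a TNF receptor (1.54), Lmtk3 (1.48), Hjv (1.40) and the aldolase Aldoc (1.38). Of the ISR lists, amino acid and one-carbon synthesis had 8 of 14 lower (12 adjusted over the list alone; median -1.13, adjusted p = 5.72e-21, and adjusted p = 0.0629 with an estimated correlation). Aldh1l2 (-2.44) and Pck2 (-1.01) were among them. Transporters had 4 lower (8 adjusted over the list alone; adjusted p = 5.38e-11, and adjusted p = 0.0629 with an estimated correlation). Regulators had 5 lower (8; 7.09e-11, and adjusted p = 0.112 with an estimated correlation) and tRNA synthetases 8 (12; 6.01e-11, and adjusted p = 0.19 with an estimated correlation). Glycolysis rose, with 6 of 20 genes higher and 13 adjusted over the list alone (median 0.34, adjusted p = 2.18e-14, and adjusted p = 0.0629 with an estimated correlation). Ldha (0.46 ± 0.07), Pgk1 (0.39 ± 0.08) and Pfkp (0.46 ± 0.09) were among them. Atrial markers were higher (1 rose, Mybphl at 1.05 ± 0.19, and 4 adjusted over the list alone, adjusted p = 0.000839, and adjusted p = 0.0629 with an estimated correlation). Cytosolic ribosomal proteins were higher too (0 rose, median 0.16, adjusted p = 5.03e-09, and adjusted p = 0.694 with an estimated correlation). Nuclear-retained RNAs were higher beside them (1 rose, 2 adjusted over the list alone, median 0.29, adjusted p = 0.0134, and adjusted p = 0.357 with an estimated correlation), a call lost without knockout 3 or double 3 (0.282 and 0.0571). ER unfolded protein response genes were higher with no member called (median 0.23, adjusted p = 0.00176, and adjusted p = 0.694 with an estimated correlation). Mural markers were likewise higher (adjusted p = 0.0493, and adjusted p = 0.19 with an estimated correlation), and fibroblast markers lower with no member called (median -0.5, adjusted p = 0.00258, and adjusted p = 0.661 with an estimated correlation). The call of fibroblasts was lost without knockout 3 (0.478), that of the ER list without knockout 3 or double 3 (0.0614 and 0.0507) and that of mural markers in 4 of 6 such fits (0.0507 to 0.0967).

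In that comparison 122 genes were called, 62 higher and 60 lower. The count was 52 without knockout 1, 327 without knockout 3, and 55, 49 and 29 without double 1, 2 and 3, and it was 66 with only these groups fitted, 58 with a sex term and 317 with DESeq2. All 32 named genes called had groups that did not overlap (10% by chance), and 13 stayed called whichever library was left out, among them Asns, Mthfd2, Trib3, Phgdh, Slc7a3, Trim66, Hjv, Rnf17, Aldh1l2 and Pck2. Others lost the call, Atf4 without double 1 or 3 (adjusted p = 0.0711 and 0.0719), Atf5 without double 1, 2 or 3 (0.081 to 0.109) and Psat1, Ldha and Lmtk3 without double 3 (0.0621, 0.0507 and 0.0588). Cyb5r2 lost it without knockout 1 (0.0542), and Chac1 and Slc7a11 when any library but double 2 was left out (0.0501 to 0.101). Zfp990 and Pfkp lost it when any library but knockout 3 was left out (0.0786 to 0.146), Akr1e1, Tnfrsf1b and Pgk1 without knockout 1 or double 1, 2 or 3 (0.0517 to 0.121), Aldoc without knockout 2 or double 1, 2 or 3 (0.0585 to 0.103) and Mybphl without knockout 1 or double 1 or 3 (0.0542 to 0.0765).

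Against the Eif2a mutant, with which it shares that mutation, the FST double showed how the Ptpmt1 knockout acted on the mutant background. Ptpmt1 was the 1 gene called, with 1131 at an unadjusted p under 0.05 and 1 with edgeR. DESeq2 called 22, without Ptpmt1, to which it gave no adjusted p. Asns (0.27 ± 0.15, adjusted p = 0.64), Mthfd2 (0.04 ± 0.17, 0.963), Trib3 (-0.68 ± 0.34, 0.623) and Atf4 (0.17 ± 0.13, 0.709) were not called. The 25 ISR-list genes that rose in the Ptpmt1 knockout had a median log2 fold change of 1.06 there and -0.0152 here, comparisons that share no library. Erythroid markers were lower as a list (0 fell, median -0.57, adjusted p = 0.00525, and adjusted p = 0.917 with an estimated correlation). Endothelial markers were higher (0 rose, 3 adjusted over the list alone, median 0.14, adjusted p = 0.0136, and adjusted p = 0.917 with an estimated correlation), a call lost without Eif2a mutant 2 (0.0505). The interaction, which tests the difference of both effects, called Trib3 (-4.63 ± 0.48, adjusted p = 0.000525), Asns (-2.09 ± 0.22, 0.000525) and Mthfd2 (-1.84 ± 0.25, 0.00835), each of which stayed called whichever library was left out, while with a sex term 2 were called and Mthfd2 was not (adjusted p = 0.0784). All 25 genes had an interaction below 0, with a median of -1.07, but they were picked in libraries that enter the interaction. As lists, amino acid and one-carbon synthesis (2 lower, 12 adjusted over the list alone, adjusted p = 1.65e-24, and adjusted p = 0.0587 with an estimated correlation) and ISR regulators (1 lower, 8 adjusted over the list alone, adjusted p = 3.75e-13, and adjusted p = 0.111 with an estimated correlation) were lower. Endothelial markers (adjusted p = 0.00851, and adjusted p = 0.472 with an estimated correlation) and cardiomyocyte markers (adjusted p = 0.036, and adjusted p = 0.472 with an estimated correlation) were higher beside them, and mitochondrially encoded genes lower (median -0.47, adjusted p = 0.0114, and adjusted p = 0.634 with an estimated correlation). The first was lost without knockout 3 (0.0638), the second without Eif2a mutant 2 or 3, knockout 2, double 2 or control 3 (0.0594 to 0.217), the last without Eif2a mutant 1, knockout 3 or control 3 (0.0819, 0.0711 and 0.449). The interaction count of 3 was 8 without control 3, 7 without Eif2a mutant 1, 5 and 35 without knockout 2 and 3 (the last 16 higher and 19 lower), 5 without double 2, 9 without the pair of libraries that stand apart, 5 with edgeR and 32 with DESeq2.

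The FST double was also compared with control, the same 3 libraries as for the Eif2a mutant, so that calls in both are not independent. Hjv (1.06 ± 0.14, adjusted p = 0.01), Slc2a3 (0.95 ± 0.12, 0.00478) and the neuronal cytoskeletal protein Crmp1 (0.84 ± 0.14, 0.0203) had the largest rises, and Ptpmt1, Tmtc1, an ER mannosyltransferase (-1.67 ± 0.24, 0.0114), and the ubiquitin ligase Trim2 (-0.94 ± 0.16, 0.0332) the largest falls. The p53 targets were higher as a list (1 rose, Ccng1 at 0.53 ± 0.08, and 4 adjusted over the list alone, median 0.35, adjusted p = 1.96e-05, and adjusted p = 0.244 with an estimated correlation). Fatty acid oxidation was lower (0 of 25 fell, median -0.21, adjusted p = 3.9e-06, and adjusted p = 0.283 with an estimated correlation). So were the TCA cycle (adjusted p = 3.7e-05, and adjusted p = 0.283 with an estimated correlation) and cardiomyocyte markers (0 fell, 4 adjusted over the list alone, adjusted p = 0.00083, and adjusted p = 0.283 with an estimated correlation). Markers of other cell types moved with these. Erythroid markers (0 fell, median -0.78, adjusted p = 0.000674, and adjusted p = 0.75 with an estimated correlation) and fibroblast markers (0 fell, 1 adjusted over the list alone, median -0.26, adjusted p = 0.0318, and adjusted p = 0.75 with an estimated correlation) were lower. The first was lost without control 2 (0.0903), the second without double 2 or 3 or control 1 or 2 (0.0657 to 0.304). Atrial markers were higher (1 rose, 2 adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.283 with an estimated correlation), a call lost without double 1 or 3 or control 1 (0.0565, 0.0544 and 0.102). Nuclear-retained RNAs were higher (1 rose, Meg3 at 0.5 ± 0.09, adjusted p = 0.000435, and adjusted p = 0.283 with an estimated correlation). Asns (0.29, 0.556), Atf4 (0.23, 0.574) and Trib3 (1.05, 0.308) were not called. Limma called 20 genes, 10 each way, none in the ISR lists, and the groups of all 10 named ones did not overlap (10% by chance). The count was 3, 4, 9, 6 and 4 without control 1, control 2 and double 1, 2 and 3, 11 with a sex term, 9 without the pair of libraries that stand apart and 93 with DESeq2. Slc2a3 stayed called whichever library was left out, and Hjv was not called without control 1 or 2 (adjusted p = 0.0732 and 0.0645). Ccng1 lost its call without double 1 or 3 or control 1 (0.0641 to 0.0732), Tmtc1 without double 1 or 2 or control 1 or 2 (0.0641 to 0.0946), Trim2 without double 2 or 3 or control 1 or 2 (0.153 to 0.215). Crmp1 was called only without control 3 (otherwise 0.0731 to 0.171) and Meg3 only without control 1 (otherwise 0.0655 to 0.189).

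The libraries labelled Hri knockout, with the Ptpmt1 gene intact, differed from PHT controls in 3 genes. Rec8, a meiotic cohesin, rose from 100.1 ± 4.95 to 376 ± 67.7 (1.89 ± 0.25, adjusted p = 0.0307, n = 2 and 2), and Amph, an endocytic protein (-2.66 ± 0.37, 0.0307), and the epithelial factor Grhl1 (-1.20 ± 0.17, 0.0307) fell. Both groups differed in sex in every library, and with a sex term limma called 0 genes. The main count of 3 stands beside 485 at an unadjusted p under 0.05, 3 with edgeR and 4 with DESeq2, and it was 1 without control 1, 0 with no filter and 19 with only these groups fitted. Immediate early genes were higher as a list (0 rose, 2 adjusted over the list alone, median 0.30, adjusted p = 0.000408, and adjusted p = 0.375 with an estimated correlation), with Fos at 0.88 (adjusted p = 1). Macrophage markers (0 rose, 3 adjusted over the list alone, median 0.69, adjusted p = 0.00109, and adjusted p = 0.708 with an estimated correlation) were higher in the same libraries. So were endothelial markers (0 rose, median 0.13, adjusted p = 0.00135, and adjusted p = 0.186 with an estimated correlation). Mitochondrially encoded genes were higher too (0 rose, 1 adjusted over the list alone, median 0.23, adjusted p = 0.0017, and adjusted p = 0.915 with an estimated correlation), a call lost without Hri knockout 1 or control 1 (0.396 and 0.736). The eIF2 kinase list was lower (0 fell, 1 adjusted over the list alone, Eif2ak1, adjusted p = 0.0362, and adjusted p = 0.375 with an estimated correlation). The macrophage call was lost without Hri knockout 2 or control 2 (0.328 and 0.0622), the endothelial without Hri knockout 1 (0.0621) and the kinase list without Hri knockout 1 or control 1 or 2 (0.114 to 0.352). Each gene's groups did not overlap (33.3% by chance), but Amph lost its call without Hri knockout 1 or control 1 or 2 (adjusted p = 0.139 to 0.649), and Grhl1 and Rec8 whichever library was left out (0.0721 to 1). The ISR regulators were higher as a list with no member called (median 0.17, adjusted p = 0.00584, and adjusted p = 0.915 with an estimated correlation), a call lost without Hri knockout 1 or control 2 (0.108 and 0.412). Asns (-0.21), Atf4 (0.00) and Trib3 (-0.46) had adjusted p = 1.

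In the doubles labelled Ptpmt1 and Hri knockout, ISR genes were again lower than in the Ptpmt1 knockout. Asns was at 267 ± 62.1 in the double (n = 2) against 1366 ± 259 in the Ptpmt1 knockout (n = 3; -2.36 ± 0.17, adjusted p = 1.42e-05), Mthfd2 at 344 ± 43.0 against 1247 ± 250.1 (-1.84 ± 0.16, 1.87e-05) and Atf5 at 169 ± 9.27 against 789 ± 168 (-2.20 ± 0.17, 1.42e-05). Atf4 (-0.87 ± 0.12, 0.00212), Trib3 (-3.39 ± 0.43, 0.00113), Phgdh (-1.24 ± 0.12, 6.24e-05) and Psat1 (-0.64 ± 0.11, 0.0139) were lower too, while Ddit3 (-1.01, 0.0779) missed the threshold. The largest falls were in Chac1 (-6.83, 1 read in the doubles, ratio 314, interval 61.4 to 13596.4), Slc7a3 (-5.14), Cyb5r2 (-4.60), Slc7a11 (-4.11), Trim66 (-3.61) and Trib3. By list, 11 of 14 amino acid and one-carbon genes fell (13 adjusted over the list alone; adjusted p = 1.09e-39, and adjusted p = 0.065 with an estimated correlation). So did 5 of 16 regulators (12; 1.07e-22, and adjusted p = 0.103 with an estimated correlation), 5 of 9 transporters (7; 1.27e-17, and adjusted p = 0.065 with an estimated correlation) and 9 of 20 tRNA synthetases (12; 5.93e-19, and adjusted p = 0.103 with an estimated correlation). Among the largest rises were those of Ctse, a protease of red cell and stomach (6.05 ± 1.06, adjusted p = 0.0187), the globin gene Hbb-bs (2.28 ± 0.39, 0.0158), the spectrin Sptb (0.87), the kinase Sgk3 (0.80) and the tubulin Tuba1c (0.74). Erythroid markers rose as a list (1 called, 10 adjusted over the list alone, median 1.78, adjusted p = 3.86e-16, and adjusted p = 0.231 with an estimated correlation). They held 0.5% and 0.890% of the signal in the doubles. Macrophage markers were higher too (0 called, 4 adjusted over the list alone, median 0.81, adjusted p = 2.07e-05, and adjusted p = 0.304 with an estimated correlation), a call lost without double 2 (0.495). Mitochondrially encoded genes were lower with no member called (median -0.15, adjusted p = 0.0021, and adjusted p = 0.587 with an estimated correlation), a call lost without double 1 (0.235). The 5 named rises lost their calls without double 2 (adjusted p = 0.202, 0.209, 0.26, 0.222 and 0.282 in that order). Some were lost without knockout 2 (Hbb-bs 0.0596, Sptb 0.067, Sgk3 0.0901, Tuba1c 0.0895), knockout 3 (Sgk3 0.0605) or knockout 1 (Tuba1c 0.104). In all 49 genes were called, 9 higher and 40 lower, 30 of them in the ISR lists. The count was 29 without knockout 2, 91 without double 1, 32 with only these groups fitted, 29 with a sex term and 105 with DESeq2, 41 higher and 64 lower. All 27 named genes called had groups that did not overlap (20% by chance), and of the falls Psat1 lost its call without knockout 2 or double 1 (0.0698 and 0.0739), Slc7a11 without knockout 2 or double 2 (0.067 and 0.0554) and Trim66 without knockout 2 (0.0814).

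The PHT doubles were also compared with the Hri knockout and with control. Besides Ptpmt1, Extl1, a heparan sulphate transferase, was lower than in the Hri knockout (-1.5 ± 0.23, adjusted p = 0.046, n = 2 and 2) and than in control (-1.79 ± 0.23, 0.0087), and Rnf17 was higher than in control (2.04 ± 0.29, 0.016). Gm9008, named after its values were seen, was the remaining call in both (ratio to control 18.9, interval 9.35 to 44.5). No ISR-list gene was called, with Asns at 0.00 ± 0.19 (adjusted p = 0.998) against the Hri knockout and -0.22 ± 0.19 (0.843) against control. The 29 ISR-list genes that rose in the PHT Ptpmt1 knockout had a median of 0.87 there and -0.00296 in the double against the Hri knockout, which share no library. Limma called 3 genes against the Hri knockout (873 at an unadjusted p under 0.05, 2 with edgeR, 11 with DESeq2) and 4 against control (984, 4 and 12), and with a sex term 0 against control. Against control, p53 targets were higher as a list (0 rose, 3 adjusted over the list alone, median 0.35, adjusted p = 2.98e-05, and adjusted p = 0.176 with an estimated correlation). Erythroid markers (0 rose, median 0.62, adjusted p = 0.00287, and adjusted p = 0.898 with an estimated correlation) and macrophage markers (0 rose, median 0.74, adjusted p = 0.016, and adjusted p = 0.898 with an estimated correlation) were higher in the same libraries. Both were lost without double 2 (0.515 and 0.719, the latter with its direction turned) or control 2 (0.152 and 0.24). Against the Hri knockout, ribosomal proteins were higher (median 0.10, adjusted p = 6.27e-08, and adjusted p = 0.944 with an estimated correlation), a call lost without Hri knockout 1 (0.43), while without double 2 the list was called lower (adjusted p = 0.00199). Mitochondrially encoded genes were lower there (0 fell, 3 adjusted over the list alone, median -0.27, adjusted p = 0.0232, and adjusted p = 0.944 with an estimated correlation), a call lost without Hri knockout 1 or double 1 (0.582 and 0.382). The interaction called 18 genes, 17 of them lower and 10 in the ISR lists. First by p were Chac1 (-8.71 ± 0.82, adjusted p = 0.00049), Atf5 (-2.31 ± 0.26, 0.00186), Asns (-2.14 ± 0.26, 0.00315), Mthfd2 (-1.84 ± 0.23, 0.00407), Aldh1l2 (-1.58 ± 0.20, 0.0043) and Slc7a5 (-1.25 ± 0.17, 0.006). As lists, amino acid and one-carbon synthesis (5 lower, 12 adjusted over the list alone, adjusted p = 7.77e-31, and adjusted p = 0.106 with an estimated correlation) and ISR regulators (2 lower, 11 adjusted over the list alone, adjusted p = 4.54e-25, and adjusted p = 0.112 with an estimated correlation) were lower. Beside them erythroid markers were higher (median 1.54, adjusted p = 5.67e-10, and adjusted p = 0.386 with an estimated correlation) and endothelial markers lower (adjusted p = 0.00591, and adjusted p = 0.172 with an estimated correlation), the latter lost without Hri knockout 1 (0.0625). Mitochondrially encoded genes were lower too (0 fell, 4 adjusted over the list alone, median -0.38, adjusted p = 3.35e-06, and adjusted p = 0.546 with an estimated correlation), a call kept whichever library was left out. Without control 1 the interaction called 2, without control 2 8, without Hri knockout 2 9, without knockout 2 7, and with DESeq2 38. Without control 1 Asns, Mthfd2 and Aldh1l2 (0.0532 each) and Slc7a5 (0.0554) were not called, nor Aldh1l2 and Slc7a5 without control 2 (0.0565 each). Without 1 library, Extl1 lost its call against control without double 2 or either control (0.107 to 0.207) and against the Hri knockout without either Hri knockout or double 2 (0.06 to 0.299). Rnf17 lost it without double 2 or either control (0.0507 to 0.327). The counts went from 0 without double 2 to 8 without double 1 against control, with 1 without control 1 and 1 without control 2. They went from 0 without Hri knockout 2 to 10 without double 1 against the Hri knockout, with 7 without Hri knockout 1 and 1 without double 2.

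The PTGC doubles, labelled Ptpmt1 and Gcn2 knockout, were compared with their controls. Here the ISR genes were high. Asns rose from 349 ± 30.2 to 2181 ± 172 (2.64 ± 0.11, adjusted p = 3.28e-07, n = 3 and 3), Mthfd2 from 441 ± 25.4 to 1968 ± 124 (2.16 ± 0.10, 6.68e-07), Trib3 from 25.1 ± 8.07 to 654 ± 95.6 (4.69 ± 0.23, 8.24e-07) and Atf4 from 1277 ± 34.2 to 2954 ± 349 (1.20 ± 0.11, 6.48e-05). Atf5 (2.65), Ddit3 (1.85), Phgdh (1.63), Psat1 (0.90) and Gdf15, a secreted stress factor (2.62 ± 0.32, adjusted p = 0.0012), rose as well. The largest rises were in Trim66 (6.16), Slc7a3 (5.25), Chac1 (5.21), the neuronal adhesion gene Cntnap3 (5.15, 2 reads in the controls, ratio 77.4, interval 22.0 to 669), Trib3 and Cyb5r2 (4.20). Among the largest falls after Ptpmt1 were those of Gtsf1 (-0.95 ± 0.17, adjusted p = 0.0259), Igfbpl1 (-0.65), Tmem50b (-0.53) and Nudt4 (-0.45). Of 16 ISR regulators 12 rose (16 adjusted over the list alone; median 1.71, adjusted p = 6.72e-38, and adjusted p = 0.0268 with an estimated correlation), among them Sesn2, a leucine sensor (2.01 ± 0.12). Amino acid and one-carbon synthesis had 12 of 14 higher (14 adjusted over the list alone; median 1.5, adjusted p = 3.21e-41, and adjusted p = 0.0268 with an estimated correlation). Transporters had 7 of 9 higher (8 adjusted over the list alone; adjusted p = 3.53e-23, and adjusted p = 0.0268 with an estimated correlation), and tRNA synthetases 9 of 20 (13; 1.67e-14, and adjusted p = 0.168 with an estimated correlation).

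Several lists were lower in the PTGC doubles with few members called. Cell cycle genes were (0 of 22 fell, 5 adjusted over the list alone, median -0.24, adjusted p = 6.01e-09, and adjusted p = 0.2 with an estimated correlation). So were mitochondrial ribosomal proteins (0 of 78 fell, median -0.13, adjusted p = 2.36e-06, and adjusted p = 0.365 with an estimated correlation). Complex I (0 fell, median -0.15, adjusted p = 4.62e-07, and adjusted p = 0.365 with an estimated correlation) and complexes II to V (7.01e-07, and adjusted p = 0.365 with an estimated correlation) were lower as well. In the last list Cox6a2 rose (1.04 ± 0.15, adjusted p = 0.00414) while 5 genes fell adjusted over the list alone. Mitochondrially encoded genes (0 of 8 fell, 3 adjusted over the list alone, median -0.51, adjusted p = 6.21e-05, and adjusted p = 0.365 with an estimated correlation) held 2.41%, 1.79% and 3.42% of the signal in the controls and 1.79%, 1.54% and 1.79% in the doubles. Fatty acid oxidation (1.52e-05, and adjusted p = 0.365 with an estimated correlation) and the TCA cycle (0.000144, and adjusted p = 0.365 with an estimated correlation) were lower. Nuclear-retained RNAs were higher with no member called (median 0.29, adjusted p = 0.0426, and adjusted p = 0.365 with an estimated correlation), a call lost without double 1 or control 2 or 3 (0.231, 0.0733 and 0.167). Erythroid markers stood beside the lower lists (median -0.77, adjusted p = 5.4e-07, and adjusted p = 0.365 with an estimated correlation). Mitochondrial dynamics was lower too (median -0.20, adjusted p = 0.0359, and adjusted p = 0.365 with an estimated correlation), a call lost without double 2 or control 1 or 3 (0.0707, 0.0893 and 0.121). The p53 targets were higher, with Cdkn1a, the inhibitor of cyclin-dependent kinases, rising by 1.03 ± 0.16 (list adjusted p = 0.0181, and adjusted p = 0.264 with an estimated correlation), a list call lost without control 2 (0.0927). The mitochondrial protease Lonp1 (0.72 ± 0.10, 0.00306) and Herpud1 (0.91 ± 0.13, 0.00414) rose, while their lists, mitochondrial proteostasis (0.798) and the ER response (0.324), were not called. In all 105 genes were called, 99 higher and 6 lower, 40 of them among 59 tested members of the ISR lists, and all 33 named ones had groups that did not overlap (10% by chance). The count was 67 without double 1, 57 without double 3 and 536 without control 2, 285 higher and 251 lower, and 179 with DESeq2, 136 higher and 43 lower. Calls were lost without double 3 for Cdkn1a (0.072), Cox6a2 (0.0593) and Herpud1 (0.0631), and without control 1 or double 1, 2 or 3 for Gtsf1, Igfbpl1, Tmem50b and Nudt4 (0.0733 to 0.32). The PTGC table has no Ptpmt1 knockout with Gcn2 intact, so the share of the second mutation in these changes could not be tested.

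**Figure D3:**
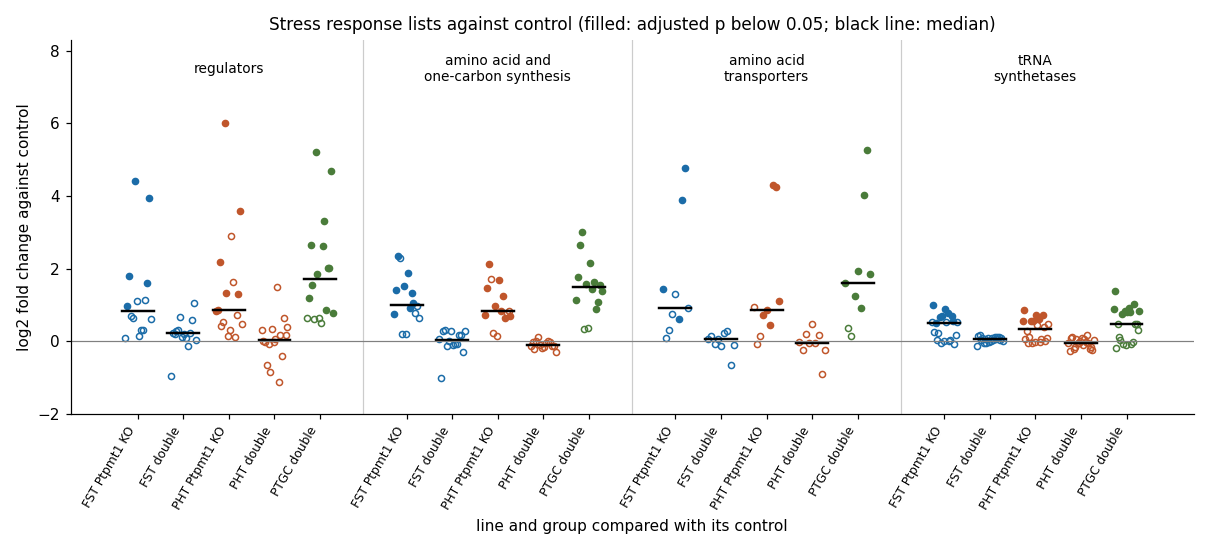
Log2 fold changes against control of the tested members of the 4 ISR lists, 1 point per gene with the list median as a line, for the Ptpmt1 knockouts and doubles of the 3 lines, filled where the adjusted p was under 0.05. The amino acid and one-carbon median is 1.01 in the FST knockout and 0.84 in the PHT knockout, 0.04 in the FST double and 1.5 in the PTGC double.

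Some lists were not called in any comparison. Cardiolipin synthesis, to which Ptpmt1 belongs, had a lowest adjusted p of 0.0781, and Ptpmt1 was the 1 member that fell. Fetal and stress genes of the heart (lowest adjusted p 0.224), Nrf2 targets (0.125), interferon response (0.299) and mitochondrial proteostasis (0.296) were not called either. Lymphocyte, Schwann cell and adipocyte markers had fewer than 3 tested genes, so no test was run. Sex-linked genes were called in 6 of the 13 comparisons. Fibroblast markers were called in 2, endothelial markers in 4 and cardiomyocyte markers in 3, and of the 84 higher and 59 lower list calls 5 were kept with an estimated correlation. These are those of amino acid and one-carbon synthesis and of transporters in the PHT knockout and of these and the ISR regulators in PTGC.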

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

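The tests of a less complete loss of Ptpmt1, of the zinc finger genes and of Eif2ak1 were chosen only after the results they measure were seen. The bound for loss of Ptpmt1 as the cause of the signs of Zfp979 was changed after its value was seen, from calls of both signs to calls that also hold whichever library is left out, which turned an exclusion into an open result. The sex term, and leaving out 2 FST libraries, were tests added after the data were seen. What drew attention was that the same knockout of Ptpmt1 had another effect in libraries with a second mutation, tested as an interaction. It called 3 genes in FST, Trib3 (-4.63), Asns (-2.09) and Mthfd2 (-1.84), and 18 in PHT, first by p Chac1 (-8.71), Atf5 (-2.31), Asns (-2.14), Mthfd2 (-1.84), Aldh1l2 (-1.58) and Slc7a5 (-1.25). Of 100 splits of the 12 FST libraries, the real one included, 3 called at least as many genes as the real one with its 3. The highest other called 170, and the makeup of that split was not examined. These splits shuffled all groups at once, so effects of the real groups can enter the interaction of another split. They do not test the interaction alone, and chance is not excluded. PHT has groups of 2, for which splits were not counted.

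The ISR genes that rose without Ptpmt1 had medians of -0.0152 in the FST double and -0.00296 in the PHT double against their single mutants. Sex as the whole cause is argued against in FST. With a sex term the median interaction over these genes was -1.16 there (-1.32 to -1.02 with 1 library left out), although Mthfd2 lost its call (-1.95, adjusted p = 0.0784). In PHT it was -1.05 (-1.15 to -0.94). Only the Ptpmt1 knockout group holds both sexes there, with a male pattern in 1 of 3 libraries. Without that library no sex term can be fitted, so the PHT range leaves that fit out and sex stays open in PHT. Without both FST libraries that stand apart the FST median interaction was -1.05 (-1.19 to -0.93 with 1 more library left out). These libraries therefore do not carry it, although the genes were picked in libraries that enter these medians. A less complete loss of Ptpmt1 in the doubles is argued against only for a response that scales with the transcript lost. The median ratio of their response to that of the knockout was -0.0100 in FST and -0.00138 in PHT, where 0.910 and 0.867 of the loss of transcript was reached. The doubles kept 28.8% and 29.3% of the single mutants' transcript, the knockouts 21.8% and 18.4% of control. A response that needs a loss beyond some level was not tested and stays open. That the response needs intact eIF2 alpha in FST remains a hypothesis, which new libraries with both sexes in each of the 4 groups could decide by the interaction over the same 25 genes, while in PHT the part of Hri stays open with the doubt about its label.

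Zfp979 had calls in opposite directions in 2 lines, at 2.15 ± 0.41 in the FST Ptpmt1 knockout and -1.78 ± 0.34 in the PHT one, and the difference between tables was not tested. An effect of the loss of Ptpmt1 itself, the biological explanation that the design gives, cannot be told apart for this gene: the share of the 5 contrasts against control with the majority sign was 0.6, but the gene was singled out for its signs and its PHT call was lost whichever library was left out (adjusted p = 0.0537 to 0.537). A strain variant that segregates in the mice could be the source, as the spread within groups of zinc finger genes in that part of chromosome 4 lay at the median percentile of 85.8 of genes with like means, over 26 pairs of gene and table. That explanation cannot be told apart from others for these genes, because the value lies between both bounds set for it and the tables hold no genotypes.

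Eif2ak1 transcript was at 70.8% of control (59.0 to 84.9) in the single Hri knockout and hardly lower in the double, which had 126% (105 to 152, unadjusted) of the single, with an adjusted p of 0.785 for that difference. RNA of cells that keep the gene might raise it, but Eif2ak1 stood at 89.5% of control (74.6 to 107) in the doubles, where Ptpmt1 was at 29.6% (20.8 to 42.1). Other cells would have to hold most of the Eif2ak1 RNA, and with no values from sorted cells this cannot be told apart for that gene. Doubles that match the Ptpmt1 knockouts in all but the label are argued against, as the ISR genes called in the knockout had a median of -0.0314 against control there (-0.115 to 0.0230 with 1 library left out). That does not show that Hri was lost, since sex pattern and mean Ptpmt1 left also differed between these groups. A deletion that leaves most of the transcript stays open, since values per gene hold no exon counts.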

How the results depend on the processing

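The sex term and leaving out both FST libraries that stand apart were tests chosen after seeing the data. Counts of called genes beyond 1.5 times the main count were these, and the cause was not tested. With DESeq2 they were 353 for the FST Ptpmt1 knockout, 47 for the Eif2a mutant, 93 for the FST double against control, 317 against the Ptpmt1 knockout, 22 against the Eif2a mutant, 32 for the FST interaction, 69 for the PHT Ptpmt1 knockout, 12 for the PHT double against control, 105 against the Ptpmt1 knockout, 11 against the Hri knockout, 38 for the PHT interaction and 179 in PTGC. With only the groups compared, which leaves fewer samples to estimate the spread, they were 27, and 66 for the FST double against the knockout, and in PHT 19 for the Hri knockout, 13, 32 and 0 for the double against control, the Ptpmt1 and the Hri knockout. The sex term gave 21, 11 and 58 for the FST knockout and the FST double against control and knockout, and in PHT 0 for the Hri knockout (limma; main 3, 485 at an unadjusted p under 0.05, edgeR 3, DESeq2 4), 0 for the double against control (main 4, 984 unadjusted, edgeR 4, DESeq2 12) and 29 against the Ptpmt1 knockout. Without a filter the Eif2a mutant had 3, the FST interaction 6, and the Hri knockout and the double against it 0 (for the double, main 3, 873 unadjusted, edgeR 2, DESeq2 11), as with a filter of 100, where the PHT double against control had 2. The FST interaction had 8 with a pseudocount of 8, 5 with edgeR and 9 without both libraries that stand apart, where the FST double against control had 9. Beside 84 higher and 59 lower list calls, an estimated correlation called 5 lists and fry 32, of which 29 were among these calls. Pearson's r between the Ptpmt1 knockouts was 0.308, and 0.554 for genes with a mean of at least 100.

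With 1 library left out, where a lone sample is assumed to vary like the other groups, counts ran from 21 to 857 for the FST knockout, 2 to 6 for the Eif2a mutant, 3 to 26, 29 to 327 and 1 to 1 for the FST double against control, knockout and Eif2a mutant and 3 to 35 for the FST interaction. In PHT they ran from 21 to 42 for the knockout, 1 to 2 for the Hri knockout, 0 to 8, 29 to 91 and 0 to 10 for the double against control, Ptpmt1 and Hri knockout and 2 to 22 for the interaction, in PTGC from 57 to 536, and for list tests from 127 to 161. The highest count came without Ptpmt1 knockout replicate 3 in FST. List directions turned, with adjusted p and its range over libraries left out, without FST control 3 for mitochondrially encoded genes in the Eif2a mutant (0.207, range 4.39e-05 to 0.207) and without Hri knockout 1 for ribosomal proteins in that group (0.0944, range 8.81e-08 to 0.513). Without PHT double 2 they turned against control for complex I (0.333, range 1.52e-10 to 0.333), complexes II to V (0.990, range 1.83e-11 to 0.990), ribosomal proteins (2.96e-07, range 5.16e-25 to 0.206) and macrophages (0.719, range 1.7e-06 to 0.719). They also turned against the Ptpmt1 knockout for complex I (0.0241, range 3.2e-09 to 0.102) and complexes II to V (0.0638, range 8.5e-08 to 0.226), against the Hri knockout for ribosomal proteins (0.00199, range 1.67e-35 to 0.430) and in the interaction for the cell cycle (0.974, range 2.32e-07 to 0.974). Of the 184 calls of named genes, 22 were lost with no filter, 57 with a sex term, 4 with edgeR, 7 with a pseudocount of 0.5 and 1 with 8, and of 1086 values with 1 library left out 794 kept the call, and no direction turned. TMM scaling moved medians by 0.0239 or less and kept every list call. No paired analysis was possible because titles give every library its own identifier and no numbers shared between groups. The low depth of FST double 2, where 1 read counts as 4.42, limits genes near the floor.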

Other observations

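The test of genes near the targeted loci, and some pairs of correlated comparisons, were chosen only after the results were seen. Trim66 and Cyb5r2, outside the ISR lists, had calls in all 3 lines: Trim66 rose by 6.16 ± 0.78, 5.81 ± 0.57 and 6.16 in the FST knockout, PHT knockout and PTGC double, and Cyb5r2 by 3.60, 3.19 and 4.20 (adjusted p = 0.00171, 8.89e-05 and 2.44e-06 for Trim66). The p53 targets were higher as a list in comparisons of all 3 lines, though in none with an estimated correlation. Comparisons within a line share libraries, and the call was lost without knockout 3 in the FST knockout (adjusted p = 0.109), without knockout 3 or control 2 in the PHT knockout (0.188 and 0.14) and without control 2 in PTGC (0.0927). Of its members Cdkn1a was at 0.74 (adjusted p = 0.089) in the FST knockout and 1.03 (0.00668) in the PTGC double. Log2 fold changes of the PTGC double had Pearson's r of 0.148 with the FST knockout and 0.285 with the PHT one, with jackknife SEs of 0.282 and 0.194. Spearman's rho was -0.165 and -0.0364, and r without called genes -0.0761 and 0.0438, values without SEs of their own, so agreement beyond the called genes stays open. Of the called genes 32 and 37 were higher in both, where 0.284 and 0.273 would be by chance.

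The 6 libraries of 2 groups of 3 make 10 splits, the real one included, too few for a share under 0.05. As many genes as the real split came from 2 splits for the FST knockout, itself among them (real 70, highest other 145). In the other comparisons it was 1, the real split itself: the Eif2a mutant (5, highest other 1), the FST double against control (20 and 6), the knockout (122 and 3) and the Eif2a mutant (1 and 0), and PTGC (105 and 1). The split with 145 set controls 1 and 2 and knockout 3 against control 3 and knockouts 1 and 2, which points to a structure of the samples. It parts them by the share of erythroid genes in the signal, 0.233%, 0.306% and 0.233% against 0.0862%, 0.0779% and 0.0917%. Whether that share or another trait made the split was not tested.

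Variants carried along with the targeted loci might explain some calls outside the ISR lists. Of 90 such calls 2 lay within 20 megabases of a targeted locus, against 2.45 given by the share of tested genes, a ratio of 0.816 for the doubles, the Eif2a mutant and the Hri knockout against control. For the FST double against the Ptpmt1 knockout it was 5 of 94 against 2.49 (Fisher p = 0.104). Of these 5, named for their position, Pygl, 4930447C04Rik, Gm10451 and Sptb lay at 70190811 to 76710547 on chromosome 12, near Eif2s1 at 78861819. Dgkz lay near Ptpmt1 on chromosome 2, a locus knocked out in both groups. The 2.49 counts both windows, so the Eif2s1 locus was not tested alone. In the pooled count PTGC gave 63 of the 90 calls. Both counts point opposite ways and rest on few genes, so such variants cannot be told apart from none.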
